A study of Rattus norvegicus with 8 samples.

How the data were processed

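Single nuclei of frozen retina from 2 adult wild-type rats were profiled with 10x Genomics 3′ v3.1 chemistry and sequenced on a NovaSeq. Of the 8 libraries, 4 came from animal 1 (1 unsorted, 1 CHX10-sorted, 2 NeuN-sorted) and 4 from animal 2 (2 NeuN-high, 2 NeuN-low). The deposited matrices hold raw UMI counts per gene and nucleus barcode, made by the authors with Cell Ranger 6.1.2 (per the file headers) on build mRatBN 7.2 (per the submitters' processing notes). The gene annotation, the intron setting and the barcode filter are not given in the sources used here. All libraries share 1 list of genes, and no barcode held fewer than 500 UMIs. Genes were used by the names in the files, and those that carry only an Ensembl identifier took part in the tests but were not named. Coordinates were not used, because the gene table at hand belongs to another assembly. Chat, Slc18a3, Tac1 and other list members that no symbol matched were not analysed here.

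Nuclei with fewer than 400 genes or more than 5% mitochondrial UMIs were removed (330). Likely doublets were marked per library by the share of simulated nucleus pairs among each nucleus's neighbours, and the highest-scoring nuclei, 0.8% for each 1000 nuclei of the library, were removed (2953, or 2.01% to 6.86% per library), which left 49647 nuclei. Counts were divided by the UMIs of each nucleus and log-transformed, and 3000 variable genes, 40 principal components, 20 neighbours and Leiden clustering at resolution 1 gave the classes. Clusters were named by the class whose fixed marker genes scored highest above a baseline. Amacrine nuclei were clustered again at resolution 2 with genes standardised within each animal. Subclasses and types were named from fixed markers. The baseline for naming a class and the evidence an amacrine cluster needed were set after seeing the data, as was leaving the class markers out of the list tests. Classes were made from the same counts that were then compared, so that gene tests between classes are partly circular.

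Class shares were given per library with exact (Clopper-Pearson) 95% binomial intervals, and ratios of cluster shares with 95% intervals conditional on the sum of the counts. Ratios of the sort antigen genes were given with 95% intervals from a normal approximation to the log ratio of counts. A count of 0 was read as up to 3 counts. Intervals and floors cover counting error only. Cluster shares in NeuN-high and NeuN-low libraries were compared by the log2 ratio of pooled shares. A cluster was called higher when this was at least 1 in size and of 1 sign over all library pairs with a value. Clusters with no such pair were called by their lower bound alone. Levels in CPM are UMIs of a gene per 1000000 UMIs of the library, class or cluster. A pseudocount of 5 CPM was added to cluster levels before a log or a fold was taken. Pearson and Spearman correlations across clusters were descriptive.

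For each class comparison, UMI counts were summed per animal and class, which gave 4 sums. Both classes came from the same animals, so that the animal was fitted as a block. Within an animal, however, classes could come from different gates. Bipolar nuclei came mostly from the CHX10-sorted (5992) and NeuN-low libraries (5910), amacrine nuclei mostly from the NeuN-sorted (8246) and NeuN-high libraries (10351). The block does not separate class from gate, library or free RNA of the library. NeuN-high and NeuN-low amacrine nuclei were summed per library (2 against 2), and their p-values measure only the spread between libraries of 1 animal. Tests used edgeR 4.0.16 (quasi-likelihood F test, TMM factors, its default filter on low counts) in R 4.3.3. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 with an absolute log2 fold change of at least 1. The SE of a fold change is its absolute value divided by the square root of the F statistic. It rests on a variance shared over genes and is not the spread between the animals or libraries. Fixed gene lists (29) were tested with camera of limma 3.58.1 with a preset correlation of 0.01 and again with an estimated one. With an estimated correlation, camera takes its degrees of freedom from the fit on 4 sums, which leaves almost none. That setting could hardly call any list, so the lack of a call there cannot decide about a list. Lists were adjusted for multiple tests within each comparison. Named genes were, per comparison, the 10 with the largest log2 fold change in each direction among called genes with at least 50 CPM in the higher class in each animal, changed the same way in both animals (for the gates, in all library pairs), with a symbol and not among the markers of the classes compared. The 2 called members of each list with the smallest adjusted p in each direction, the sort antigen genes and 13 single genes were named as well. The groups, comparisons, call thresholds, marker genes, gene lists and rule for naming genes were fixed before the data were examined, as were the alternatives except the merging of clusters split by animal; the choices said above to be set after seeing the data were not. These rules named 93 to 113 genes per comparison, and the text prints part of them, mostly those whose call held under the alternatives, a choice made after their values were seen.

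On simulated data, both tests checked (amacrine against ganglion nuclei and the gates) recovered 100% of 200 changed genes at log2 changes of 1.5 and 2, with 3 and 1 false calls. The counts were drawn with the dispersion edgeR had fitted, and only genes above a set level were changed. Differences of gate, free RNA or cluster makeup were not simulated. The simulation therefore checks the procedure and not the real calls. The 2 libraries of each gate differed by more than sampling noise (chi-square per degree of freedom 1.71 to 2.81) and were kept apart. Alternatives were DESeq2 1.42.0, limma-voom, median-ratio factors, no filter on low counts, doublets kept, at least 1000 genes per nucleus, coarser and finer clusters, no standardisation within animals, thinned sums, no block, libraries or channel numbers as a block, and leaving out each library. No group held 3 or more libraries, so that no other splits of the samples were counted and no library was tested as an outlier. Clustering used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9 and leidenalg 0.10.2.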

Results

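The data were single-nucleus RNA profiles of frozen retina from 2 adult wild-type rats, made to describe the diversity of amacrine cells, the inhibitory interneurons of the inner retina. Nuclei were sorted by flow cytometry with antibodies to NEUN, the product of Rbfox3, to enrich ganglion cells, and to CHX10, the product of Vsx2, to enrich bipolar cells. Animal 1 gave 1 unsorted library, 1 CHX10-sorted library and 2 NeuN-sorted libraries. Animal 2 gave 2 NeuN-high and 2 NeuN-low libraries, so that each gate came from 1 animal. The 8 deposited libraries held 52930 nucleus barcodes and 244928364 UMIs (unique molecular identifiers, one per counted RNA molecule). The unsorted library held 8435826 UMIs over 2531 barcodes (median 2045 UMIs and 1184 genes per nucleus). The CHX10-sorted library held 27117603 UMIs over 6848 barcodes (median 3709 UMIs). The NeuN-sorted libraries held 38975352 and 40132695 UMIs (median 5620 and 5261 per nucleus). The NeuN-high libraries held 46003280 and 36904774 UMIs (median 5045 and 4920), and the NeuN-low libraries 23633254 and 23725580 UMIs (median 2851 and 2320). After quality filters and removal of likely doublets, 49647 nuclei remained.

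Nuclei were assigned to amacrine-like, bipolar-like, ganglion-like, horizontal-like, rod-like and cone-like classes by marker genes fixed beforehand, and these are called by the cell names below. Of all kept nuclei, 21980 (44.3%) were amacrine, 13376 (26.9%) bipolar, 5806 (11.7%) rod, 3142 (6.33%) ganglion, 851 (1.71%) horizontal and 791 (1.59%) cone nuclei, and 3701 (7.45%) took no class name. Rods were the largest class of the unsorted library at 46.9% (95% exact binomial interval 44.9% to 48.9%), followed by bipolar nuclei at 22.5% (20.8% to 24.2%) and amacrine nuclei at 17.4% (15.9% to 18.9%). Ganglion cells made up 1.39% (0.967% to 1.94%) of it. In the CHX10-sorted library bipolar nuclei made up 93.7% (93.1% to 94.3%) and amacrine nuclei 0.939% (0.717% to 1.21%). It held 0 ganglion nuclei among 6392: the exact interval reaches 0.058%, and 3 counts of the total, the limit set for a count of 0, are 0.0469%. Amacrine nuclei were the largest class in the NeuN-sorted libraries, with 67.0% and 66.4%, and ganglion cells made up 14.1% and 13.4%. In the NeuN-high libraries amacrine nuclei made up 77.2% and 76.0%, and ganglion cells 9.80% and 11.2%. The NeuN-low libraries held 38.4% and 40.6% bipolar nuclei and 17.5% and 21.0% amacrine nuclei, with 3 ganglion nuclei among 14948. Unnamed nuclei made up 8.07% of the unsorted, 1.89% of the CHX10-sorted, 6.12% of the NeuN-sorted, 5.54% of the NeuN-high and 12.6% of the NeuN-low nuclei. No test across gates was made, because each gate held libraries of 1 animal. The intervals cover counting error only. When only nuclei with at least 1000 genes were kept, the amacrine share of the unsorted library was 27.8%, over 1.5 times higher, and that of the NeuN-low libraries was 27.0% against 19.4%.

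**Figure D1:**
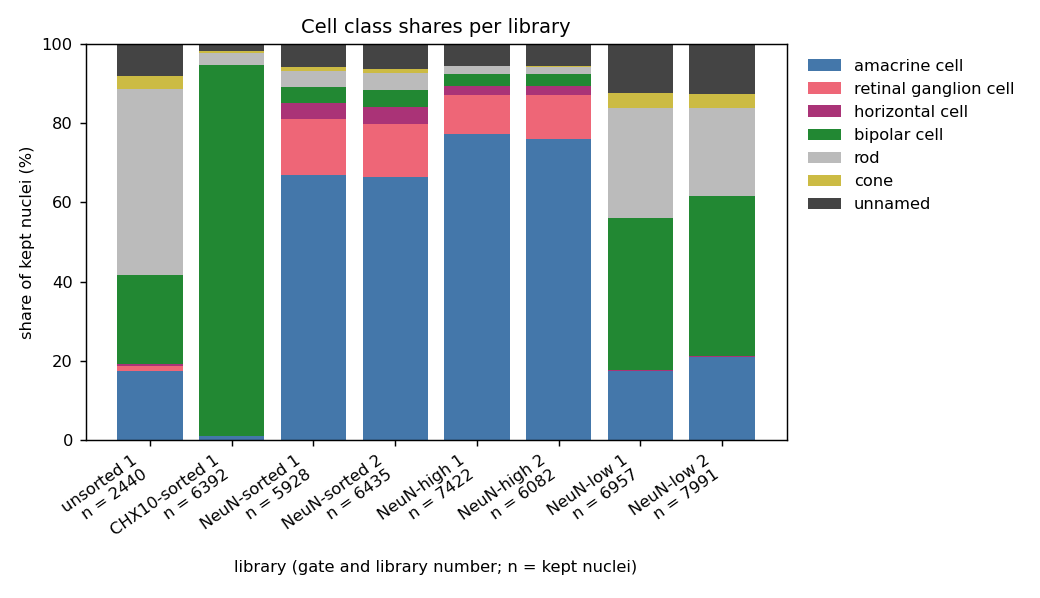
Stacked bars give the share of each class (percent of kept nuclei) in each of the 8 libraries. Amacrine nuclei fill 76.0% to 77.2% of the NeuN-high bars and 17.5% to 21.0% of the NeuN-low bars.

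The genes of both sort antigens followed the gates. Rbfox3 (ENSRNOG00000003386), which encodes a neuronal RNA-binding protein, was counted at 299 and 304 CPM (UMIs per 1000000 UMIs) in the NeuN-high libraries and at 18.2 and 19.3 in the NeuN-low libraries, a ratio of 16.1 (95% counting interval 14.99 to 17.3; 15.6 to 16.7 over the 4 pairs of libraries). In the NeuN-sorted libraries of animal 1 it reached 202 and 203 against 103 in the unsorted library, a ratio of 1.97 (1.83 to 2.11). Vsx2, which encodes a transcription factor of bipolar cells, was counted at 1374 in the CHX10-sorted library against 273 in the unsorted one, a ratio of 5.04 (4.83 to 5.26). Vsx2 was 19.1 times (18.145 to 20.045) as high in the NeuN-low as in the NeuN-high libraries. By class, Rbfox3 was highest in ganglion nuclei at 341 and amacrine nuclei at 221, and lower in horizontal nuclei at 85.2, bipolar nuclei at 15.3 and rods at 7.40. Rho, the rod photopigment gene, was counted in every class, at 1195 in rods, 224 in bipolar, 143 in amacrine and 74.8 in ganglion nuclei. Within amacrine nuclei alone, Rbfox3 stood at 308 and 309 in the NeuN-high and at 47.5 and 47.0 in the NeuN-low libraries. With every nucleus thinned to 1000 UMIs, the NeuN-sorted ratio of Rbfox3 was 3.17, over 1.5 times higher.

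Amacrine nuclei fell into 75 clusters of 21 to 1102 nuclei (median 214). By transmitter genes 54 clusters with 13637 nuclei were GABAergic and 17 clusters with 7262 nuclei glycinergic. The remaining 4 clusters (14, 24, 41 and 62; 1081 nuclei) took no subclass by that rule. They were named starburst cells, the cholinergic amacrine type, from Slc5a7, Megf10, Sox2 and Fezf1. Clusters 5 and 13 (1221 nuclei) were named AII cells, the glycinergic type that carries rod signals, and cluster 74 (29 nuclei) dopaminergic cells. Slc17a8, which encodes the vesicular glutamate transporter VGLUT3, reached 1390 CPM in glycinergic cluster 54 and at most 10.7 in any other. Th, the rate-limiting enzyme of dopamine synthesis, reached 2775 in cluster 74 and 553 in the next cluster. Vip peaked in cluster 27 (865, next 494), Sst in cluster 71 (264), Npy in cluster 40 (145, next 97.7) and Crh in cluster 23 (103), all of them GABAergic clusters and all neuropeptide genes. Gjd2, which encodes the gap junction protein connexin 36, was highest in both AII clusters (56.5 and 54.2). Nos1, the neuronal nitric oxide synthase, was highest in clusters 75 and 20 (137 and 135). Neurod6, a transcription factor gene, peaked at 6.4 in cluster 6, and Penk, which encodes enkephalins, rested on 1 UMI in its highest cluster. Chat and Tac1 were not analysed here. Of the 75 clusters, 24 drew at least 90% of their nuclei from 1 animal, against 3 of 65 clusters when genes were not standardised within each animal. In 10 pairs, clusters matched each other between the animals (correlation 0.947 to 0.977). Among them were AII clusters 5 and 13, starburst clusters 14 and 41, and starburst clusters 24 and 62. These pairs are not counted as distinct types here, and merging them also gave 65 clusters.

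**Figure D2:**
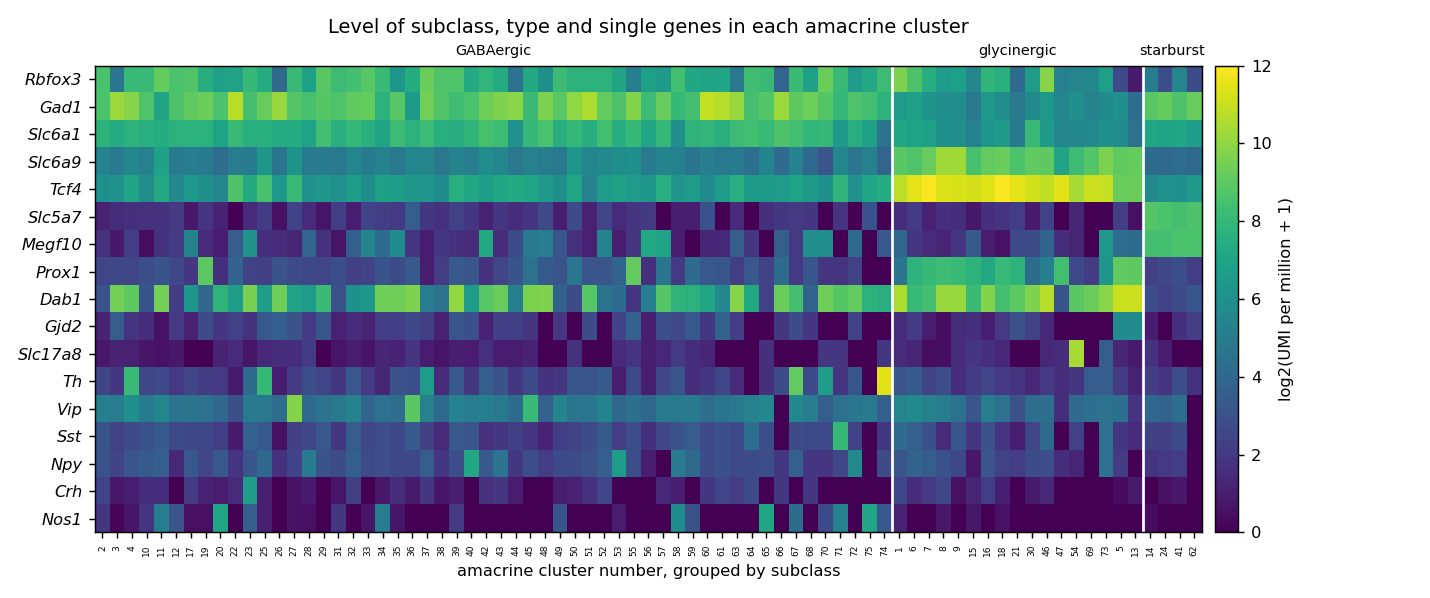
The heat map shows the level of 17 genes, as log2 of CPM plus 1, in each of the 75 amacrine clusters. Slc17a8 stands out in cluster 54 at 1390 CPM and Th in cluster 74 at 2775.

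The series design states that amacrine types express RBFOX3 unevenly, and the amacrine makeup of the NeuN-high and NeuN-low gates addressed which clusters each gate held. GABAergic clusters made up 68.1% and 68.4% of amacrine nuclei in the NeuN-high libraries and 32.1% and 34.3% in the NeuN-low libraries, while glycinergic clusters made up 30.5% and 30.3% against 61.1% and 60.4%. AII cells made up 16.9% and 17.0% of the amacrine nuclei of the low gate and 0.19% and 0.24% of those of the high gate. Starburst cells made up 6.81% and 5.23% of the low and 1.34% and 1.30% of the high gate. Dopaminergic cells gave 8 and 4 nuclei in the NeuN-high libraries and 0 of 1218 and 0 of 1681 amacrine nuclei in the NeuN-low libraries. A ratio of shares or a lower bound was obtained for 72 clusters. Of these, 40 were at least 2-fold higher in the high gate and 21 in the low gate, the same way in every pair of libraries that gave a value. Clusters without a NeuN-low nucleus gave no such pair and were counted by their lower bound alone, without a check between libraries. Clusters with nuclei in only 1 library of a gate rested on fewer pairs. With the 10 matched pairs of clusters merged, 40 of 65 clusters were higher in the high gate and 17 in the low gate. Cluster 2, a GABAergic cluster marked by Agbl1 and Crim1, held 1044 NeuN-high nuclei and 1 NeuN-low nucleus (log2 ratio 8.19, 95% interval 5.71 to 13.50). Next among clusters with NeuN-low nuclei came GABAergic cluster 11 (log2 ratio 6.92, 4.43 to 12.23), and glycinergic clusters 7 (6.50, 4.64 to 9.55) and 1 (5.92, 4.69 to 7.54). Clusters without a NeuN-low nucleus had at most a lower bound and could not be ranked. GABAergic cluster 10 had 505 nuclei against 0, a log2 ratio of at least 5.56 against a floor of 3 nuclei. At the other end stood glycinergic cluster 21, marked by Ebf1 and Lgr5 (-7.44, -8.90 to -6.30), AII cluster 13 (-6.51, -7.28 to -5.83), glycinergic cluster 47 (-6.07, -7.42 to -4.99), GABAergic cluster 22 (-5.53, -6.22 to -4.90) and glycinergic cluster 15 (-5.39, -6.01 to -4.84). Rbfox3 was counted at 798 CPM in cluster 1 and 0.85 in cluster 13, both in animal 2. Over 65 clusters with at least 20 nuclei in these gates, 13 of them placed at their lower bound, the log2 ratio went with the Rbfox3 level of animal 2 (Pearson r 0.803, Spearman rho 0.737; r 0.792 without the 2 clusters farthest from the median). With the Rbfox3 level of animal 1, whose nuclei were not in the ratios, r was 0.767 and rho 0.711 over 54 clusters (r 0.744 without the 2 farthest). Of the 8730 amacrine nuclei of animal 1, however, 8246 were NeuN-sorted. The Rbfox3 levels of both animals thus came mostly or only from nuclei sorted on its product. Clusters are not independent replicates, so no p is given. Cluster 22 and the other low-gate clusters hold few NeuN-high nuclei (6 to 28), and the intervals cover this counting error only.

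**Figure D3:**
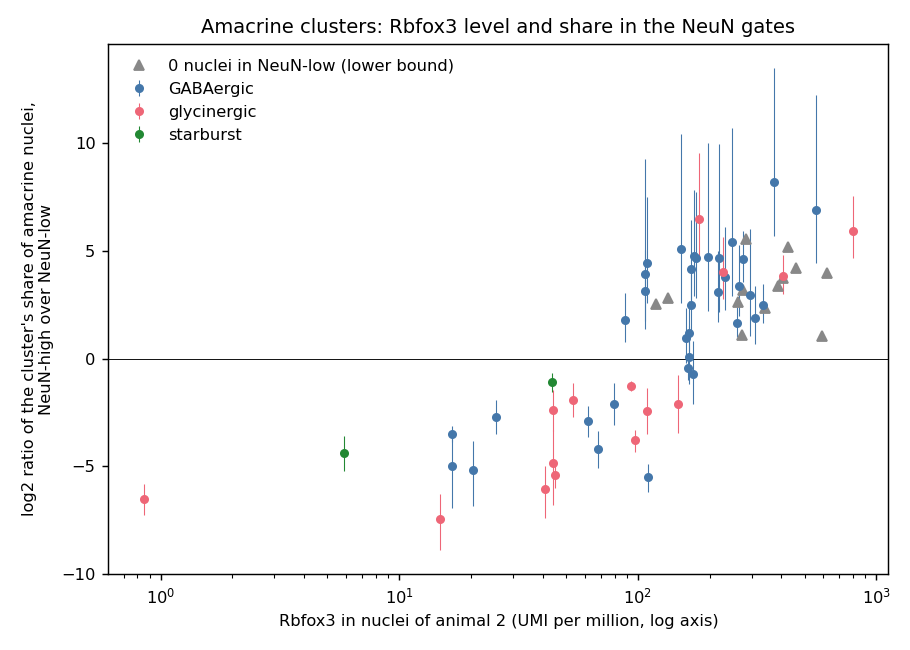
Each point is an amacrine cluster with at least 20 nuclei in these gates: the x axis gives Rbfox3 CPM in animal 2 (log axis), the y axis the log2 ratio of its share of amacrine nuclei, NeuN-high over NeuN-low, with 95% counting intervals, and triangles mark lower bounds. The 65 clusters run from -7.44 to 8.19, and the ratio went with the Rbfox3 level (r 0.803).

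Amacrine nuclei were compared with bipolar nuclei, the class that the CHX10 gate enriches, over 2 animals, and 2434 genes were higher and 1580 lower in amacrine nuclei among 16703 tested. Among glutamate receptor genes, Grin2a (ENSRNOG00000033942), an NMDA receptor subunit, was higher by a log2 fold change of 7.66 ± 0.32 (SE, n = 2 animals), and Grik3, a kainate receptor subunit, by 5.76 ± 0.13. Here and below, the SE comes from the edgeR fit, with a variance shared over genes, and is not the spread between animals or libraries. Hs6st3 (ENSRNOG00000037886), a heparan sulfate sulfotransferase, was higher by 7.80 ± 0.29 and Glra3, a glycine receptor subunit, by 6.86 ± 0.30. Lower in amacrine nuclei were the GABA-C receptor subunits Gabrr2 (-8.26 ± 0.54) and Gabrr1 (-7.24 ± 0.38) and the calcium channel genes of ribbon synapses Cacna1f (-6.42 ± 0.27) and Cacna2d4 (-6.22 ± 0.25). Of 17 ionotropic glutamate receptor genes, 13 were higher, 2 lower and 2 not called (13 and 2 adjusted over the list alone), with Grid1 among the lower ones at -2.61. Of 14 acetylcholine receptor genes, 10 were higher and 0 lower (10 and 0 over the list alone), among them Chrna7 at 2.58 ± 0.24. Of 7 metabotropic glutamate receptor genes, 5 were higher, such as Grm8 at 7.05 ± 0.61 and Grm3 at 4.85, and 1 was lower, Grm5 at -3.78 (5 and 1 over the list alone). GABA receptor genes divided, with 6 of 17 higher (Gabrb1 2.91, Gabra3 2.46), 6 lower (Gabra5 -7.29 ± 0.24) and 5 not called (9 and 6 over the list alone). Their median log2 fold change was 1.18, their mean -0.085 and the direction of the set test down. Of 30 potassium channel genes, 14 were higher and 4 lower (14 and 4 over the list alone), such as Kcnq3 at 5.77 ± 0.13. Among transcription factors, Bcl11a (5.58) and Bcl11b (4.75) were higher, and Neurod1 (-2.62) and Vsx2 (-6.85 ± 0.65), a marker that named the bipolar class, lower. Of 13 ganglion cell genes, 9 were higher and 1 lower in amacrine nuclei (11 and 1 over the list alone). Most amacrine nuclei came from the gates that also held the ganglion nuclei, and most bipolar nuclei did not. Free RNA is therefore not separated from class here. Of 17 rod genes, which mark free RNA here, 10 were lower in amacrine nuclei (10 over the list alone; median -1.07), and 8 of 13 mitochondrially encoded genes were lower (8 over the list alone). The edgeR quasi-likelihood test gave Benjamini-Hochberg adjusted p = 0.00639 for Grin2a, 0.00585 for Grik3 and 0.00801 for Gabrr2. With the preset correlation, camera gave adjusted p = 1.64e-06 for ionotropic glutamate, 6.36e-05 for acetylcholine and 0.00174 for metabotropic glutamate receptors, 0.000639 for potassium channels, 4.60e-06 for rod genes, 0.00169 for mitochondrial, 0.000321 for ganglion cell genes and 0.557 for GABA receptors. The adjusted p = 0.739 with an estimated correlation for each of these lists except GABA receptors (0.910), so that none was called. Here and in the comparisons below, that setting could hardly call any list from 4 sums. With libraries as a replicate block, the potassium channel (camera adjusted p = 0.0688) and ganglion cell gene calls (0.938) ended, and Rbfox3 was 2.37 against 3.68 ± 0.23, over 1.5 times smaller.

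Ganglion nuclei were also enriched by the NeuN gate, and amacrine nuclei differed from them in 3172 of 16499 genes, with 1691 higher and 1481 lower in amacrine nuclei. Abca13 (ENSRNOG00000025645), an ABC transporter gene, was higher by 5.88 ± 0.10 (SE, n = 2 animals), as were Nxph2 (5.49 ± 0.08), which encodes a neurexin ligand, and the transcription factors Nfix (5.26 ± 0.13) and Prox1 (4.31 ± 0.09). Slc5a7, the choline transporter of cholinergic cells, was higher by 4.88 ± 0.16 and Th by 4.01 ± 0.19. Lower in amacrine nuclei were Tbx20 (-6.98 ± 0.15), Sox6 (-5.84 ± 0.17), Foxp2 (-5.72) and Satb2 (-5.11), all transcription factor genes, and Prph (ENSRNOG00000052880), the intermediate filament peripherin, at -4.67 ± 0.10. Rbfox3 was -0.72 ± 0.16 in amacrine against ganglion nuclei and was not called, since its change stayed below the fold threshold (edgeR adjusted p = 0.0126). Of 11 neurofilament and axon genes, 3 were lower and 0 higher (3 and 0 adjusted over the list alone), namely Prph, Gap43 (-1.73 ± 0.07) and Stmn2 (-1.36). Of 8 metabotropic glutamate receptor genes, 4 were higher, such as Grm2 (3.58) and Grm3 (2.15), and 0 lower (4 and 0 over the list alone). Of 5 glycine receptor genes, Glra3 (2.74 ± 0.06) and Glra2 (1.34) were higher and 0 lower (2 and 0 over the list alone). Monoamine receptor genes were higher in 9 of 18 cases, such as Adrb2 (4.57) and Htr2c (3.01), and lower in 3 (9 and 3 over the list alone). Transcription factor genes divided evenly, with 25 of 72 higher and 21 lower (25 and 21 over the list alone). Their median log2 fold change was 0.17 and their mean -0.23. Of 17 rod genes, 2 were higher in amacrine nuclei (2 over the list alone; median 0.86), and of 12 Müller glia genes 7 were (7 over the list alone; median 1.02), among them Crb1 (2.58) and Glul (1.06). Of 9 vascular genes, 4 were higher (4 over the list alone; Flt1 4.73, Kdr 1.30), as were the microglia genes Ptprc (2.93) and P2ry12 (1.135), and the median of 13 mitochondrially encoded genes was -0.49. For Abca13, edgeR gave adjusted p = 5.99e-06. Camera gave adjusted p = 1.28e-06 for neurofilament genes, 0.00101 for metabotropic glutamate, 0.0102 for glycine and 0.000821 for monoamine receptors, 2.01e-05 for rod, 0.00370 for Müller glia, 0.0339 for vascular, 0.0261 for mitochondrial and 0.879 for transcription factor genes. With an estimated correlation, the adjusted p = 0.647 for each of these lists except transcription factors (0.874). With libraries as a replicate block, camera no longer called the metabotropic glutamate (adjusted p = 0.116), glycine (0.207) or monoamine receptor lists (0.120) or the vascular list (0.466), and without the block the mitochondrial (0.512) and vascular calls (0.0848) ended.

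GABAergic and glycinergic amacrine nuclei differed in 2060 of 15998 genes, with 1121 higher and 939 lower in GABAergic nuclei. Ccbe1 (ENSRNOG00000062986), a secreted extracellular matrix protein, was higher by 6.07 ± 0.09 (SE, n = 2 animals), the ephrin receptor gene Epha6 by 5.28 ± 0.10 and the substance P receptor gene Tacr1 by 5.27 ± 0.30. Slc6a11, which encodes the GABA transporter GAT3, was higher by 5.16 ± 0.35. Higher in glycinergic nuclei were Nxph2 (-7.29 ± 0.24), Robo3 (-6.22 ± 0.09), an axon guidance receptor, and the dopamine receptor gene Drd2 (-5.71 ± 0.36). The glycinergic side also held the transcription factors Ebf1 (ENSRNOG00000028845, -6.16 ± 0.14), Nfix (-5.86 ± 0.08) and Nfib (-5.66). Rbfox3 differed by 0.28 ± 0.15 and was not called (edgeR adjusted p = 0.241), with log2 ratios of 0.53 in animal 1 and -0.04 in animal 2. These sums pool gates that were sorted on its product, and the difference turned with the gate. In the NeuN-high libraries Rbfox3 stood at 286 CPM in GABAergic against 396 in glycinergic nuclei, and in the NeuN-low libraries at 66.7 against 41.2. Of 32 cadherin genes, 15 were higher in GABAergic nuclei, such as Pcdh11x (4.21 ± 0.07) and Cdh13 (3.21), and 3 lower, among them Cdh9 (-3.07) and Cdh12 (-2.91; 15 and 3 adjusted over the list alone). Axon guidance genes were higher in 13 of 39 cases and lower in 7 (14 and 7 over the list alone), with Sema3d (4.19) and Nrp1 (-2.91) as examples. Of 75 transcription factor genes, 20 were higher, such as Zfhx3 (4.01) and Lhx9 (3.46), 19 lower and 36 not called (20 and 19 over the list alone; median 0.06, mean -0.25, set test down). GABA receptor genes were higher in 2 of 17 cases (Gabra2 1.60, Gabbr2 1.43) and lower in 5, among them Gabrd (-5.09 ± 0.14) and Gabrg3 (-2.24; 2 and 5 over the list alone). None of the 17 rod genes (median -0.41) or of the 13 mitochondrial genes (median -0.50) was called. Among markers of other cell types, Flt1 (4.64), Ptprc (2.75) and Crb1 (1.63) were higher in GABAergic nuclei and Pdgfrb (-3.60) and Col9a1 (-2.59) lower. The edgeR adjusted p = 0.000144 for Ccbe1, 0.00159 for Slc6a11 and 0.00133 for Drd2. Camera gave adjusted p = 0.000310 for cadherins, 0.0405 for axon guidance, 0.823 for transcription factors, 0.424 for GABA receptors, 0.00228 for rod and 0.00322 for mitochondrial genes. With an estimated correlation, adjusted p = 0.893 for each of these lists. Without the replicate block the mitochondrial call ended (camera adjusted p = 0.265).

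**Figure D4:**
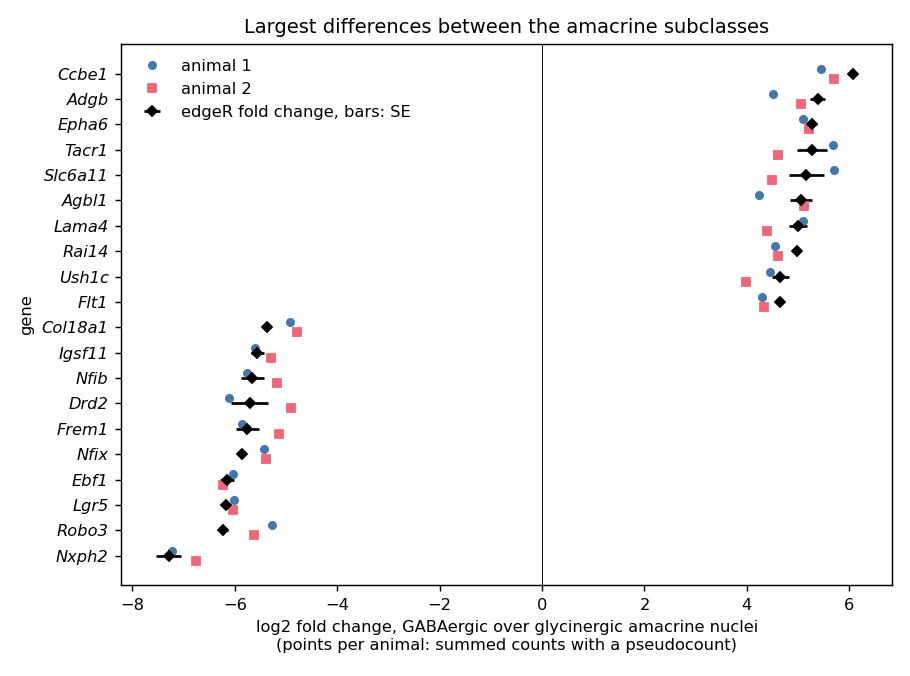
For the 10 named genes with the largest difference in each direction, diamonds give the log2 fold change from edgeR of GABAergic over glycinergic amacrine nuclei with SE, and points the ratio in each of the 2 animals. Values run from -7.29 for Nxph2 to 6.07 for Ccbe1, with both animals on the same side for each gene.

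Starburst nuclei took no subclass by the fixed rule and were compared with the nuclei of the GABAergic clusters. They stood apart by 892 higher and 2033 lower genes of 15253 tested. Clrn1 (ENSRNOG00000042477), a Usher syndrome gene, was higher by 9.25 ± 0.16 (SE, n = 2 animals), Frmd7, a gene of inherited nystagmus, by 8.43 ± 0.24, and the transcription factor Isl1 (ENSRNOG00000012556) by 6.71 ± 0.10. Starburst nuclei were also higher in the muscarinic receptor gene Chrm4 (6.23 ± 0.27) and the GABA receptor subunits Gabrd (6.31 ± 0.26) and Gabra4 (5.57 ± 0.12). They were lower in Tacr1 (-6.78 ± 0.17), the AMPA receptor subunit Gria1 (-6.67 ± 0.14), the glutamate receptor Grm1 (-6.36 ± 0.14) and Rbfox3 (-3.09 ± 0.11). Of 39 axon guidance genes, 6 were higher, such as Sema3e (2.70) and Dcc (2.10), and 26 lower, such as Slit2 (-5.14) and Epha6 (-4.96; 6 and 26 adjusted over the list alone). Among 11 sodium channel genes 0 were higher and 9 lower (1 and 9 over the list alone), among them Scn3a (-5.28 ± 0.18) and Scn1a (-3.44). Acetylcholine receptor genes were lower in 11 of 14 cases, such as Chrm2 (-4.78), with Chrm4 the 1 higher (1 and 11 over the list alone). Of 31 cadherin genes, 3 were higher (Pcdh15 3.33, Cdh6 2.96) and 18 lower (Cdh8 -5.68; 3 and 18 over the list alone). Potassium channel genes were higher in 4 of 30 cases (Kcnc2 1.21) and lower in 16 (Kcnd3 -4.69, Kcna1 -4.37; 4 and 17 over the list alone). GABA receptor genes were higher in 6 of 17 cases and lower in 5, among them Gabra3 (-4.85) and Gabbr2 (-4.12; 6 and 5 over the list alone). Their median was 0.37, their mean -0.084 and the direction of the set test up. None of the 17 rod genes was called. Among markers of other cell types, the microglia gene P2ry12 (2.97) and the Müller glia genes Col9a1 (4.93) and Sox9 (1.32) were higher. The microglia gene Ptprc (-3.03), the Müller glia gene Crb1 (-1.94) and the vascular gene Flt1 (-4.76) were lower. So were the ganglion cell genes Gap43 (-2.41) and Spp1 (-1.31), and no gene of that list was called higher. Of 13 stress genes, 6 were lower (6 over the list alone), such as Fos (-2.45). For Clrn1, edgeR gave adjusted p = 3.49e-14. Camera gave adjusted p = 1.21e-07 for axon guidance, 3.37e-06 for sodium channels, 0.000143 for acetylcholine receptors, 0.000144 for cadherins, 0.000545 for potassium channels, 0.0217 for stress genes and 0.756 for GABA receptors. With an estimated correlation, adjusted p = 0.717 for the 6 lists called. With marked doublets kept, the changes of several lower genes shrank over 1.5 times, as for the adhesion gene Kirrel3 (-6.91 to -4.22) and the NMDA receptor subunit Grin2a (-6.70 to -3.91).

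AII cells differed from other glycinergic nuclei in 2251 of 13151 genes, with 687 higher and 1564 lower. Mamdc2 (ENSRNOG00000024620), an extracellular matrix protein gene, was higher by 7.51 ± 0.21 (SE, n = 2 animals), Fgfr4, a fibroblast growth factor receptor, by 6.76 ± 0.14, and Gabrd by 6.23 ± 0.17. Scn9a, a sodium channel gene, was higher by 5.52 ± 0.12, the glycine receptor subunit Glra1 by 4.97 ± 0.22 and the adrenergic receptor gene Adrb1 by 5.22 ± 0.13. Lower in AII cells were Osbpl3 (-7.24 ± 0.20), Slc17a8 (-5.46 ± 0.29), the potassium channel gene Kcnd2 (-4.79 ± 0.14) and Rbfox3 (-5.96 ± 0.19). Of 8 metabotropic glutamate receptor genes, 7 were lower and 0 higher (7 and 1 adjusted over the list alone), among them Grm8 (-5.68) and Grm7 (-4.95). Calcium channel genes were lower in 10 of 17 cases, such as Cacnb2 (-4.24) and Cacna1a (-3.50), and higher in 3, such as Cacnb4 (1.55; 10 and 3 over the list alone). Potassium channel genes were lower in 14 of 27 cases and higher in 5, such as Kcnq3 (3.17; 14 and 5 over the list alone). Of 28 cadherin genes, 13 were lower (Cdh8 -4.56) and 2 higher (14 and 2 over the list alone), and of 21 teneurin, latrophilin and neurexin genes 10 were lower (Tenm2 -5.67) and 2 higher (Tenm4 1.80; 10 and 2 over the list alone). Sodium channel genes were higher in 3 of 11 cases, among them Scn1a (3.70), and lower in 2, among them Scn3a (-2.56; 4 and 2 over the list alone). GABA receptor genes were lower in 7 of 17 cases, such as Gabrb1 (-4.37), with Gabrd the 1 higher (7 and 1 over the list alone). None of the 16 rod genes was called. The Müller glia genes Dkk3 (-2.305) and Col9a1 (-3.47) and the stress genes Nr4a1 (-2.003) and Egr1 (-2.25) were lower and the stress gene Nr4a3 (1.42) higher. The ganglion cell genes Stmn2 (-3.10) and Gap43 (-1.55, with -0.69 in animal 1 and -3.05 in animal 2) were lower too. No gene of that list was called higher. The median of 13 mitochondrially encoded genes was 0.51 (camera adjusted p = 0.0423; 0.348 without the replicate block and 0.910 with an estimated correlation). For Mamdc2, edgeR gave adjusted p = 3.36e-07. Camera gave adjusted p = 7.97e-13 for metabotropic glutamate receptors, 1.78e-08 for calcium channels and for teneurins, 6.41e-08 for potassium channels, 1.69e-07 for cadherins and 0.00113 for sodium channels and GABA receptors. With an estimated correlation, adjusted p = 0.603 for each of these receptor, channel and adhesion lists. With marked doublets kept, 1405 genes were called, and Rbfox3 (-3.91), Grm8 (-3.13), Grm7 (-2.32), Cacnb2 (-2.07), Cacna1a (-1.92), Cdh8 (-1.96) and Tenm2 (-2.50) lay over 1.5 times nearer 0.

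Between the NeuN-high and NeuN-low gates, amacrine nuclei of animal 2 differed in 1583 of 15059 genes, with 844 higher and 739 lower in the high gate. Rbfox3 (ENSRNOG00000003386) was higher by 2.71 ± 0.06 (SE, n = 2 libraries per gate), Ccbe1 by 5.92 ± 0.13, the transcription factor Maf (ENSRNOG00000012428) by 5.03 ± 0.09 and Tac3, which encodes neurokinin B, by 4.82 ± 0.13. Lower in the high gate were Mamdc2 (-5.88 ± 0.14) and Gabrd (-4.34 ± 0.14), both higher in AII cells above, the choline transporter gene Slc5a7 (-2.36 ± 0.12), Gjd2 (-2.36 ± 0.19) and the transcription factor Ebf3 (-2.71 ± 0.06). Clusters 1 and 2 held 10.4% and 10.1% of amacrine nuclei in the high gate and 0.172% and 0.034% in the low gate. Clusters 13, 15, 21 and 22 held 15.8%, 11.4%, 10.1% and 9.80% in the low gate and 0.174%, 0.271%, 0.058% and 0.213% in the high gate. Of 32 cadherin genes, 9 were higher, such as Cdh4 (2.29) and Pcdh17 (2.21), and 2 lower, Cdh12 (-1.41) and Pcdh15 (-1.17; 9 and 2 adjusted over the list alone). Neuropeptide genes were higher in 10 of 16 cases, such as Npy (3.99 ± 0.30), and lower in 2, Nts (-1.92) and Penk (-1.41; 10 and 2 over the list alone). Of 76 transcription factor genes, 15 were higher, such as Maf, and 25 lower, such as Nfia (-2.92 ± 0.07; 15 and 25 over the list alone). Markers of other cell types moved with the gates as well. Of 12 ganglion cell genes, 9 were higher in amacrine nuclei of the high gate and 0 lower (9 and 0 over the list alone; median 2.88), such as Slc17a6 (3.50 ± 0.25), the glutamate transporter of ganglion cells, and Sncg (3.14 ± 0.11). Of 10 genes of the ON bipolar cascade, 4 were lower (4 over the list alone), such as Trpm1 (-3.30 ± 0.14), and 1 higher, Lrrtm4 (2.40). Vsx2 was lower by -2.21 ± 0.11, and 4 of 17 rod genes (4 over the list alone; median -0.68) and 4 of 12 Müller glia genes (4 over the list alone; Slc1a3 -2.26, Apoe -1.65) were lower. Genes of the vascular list divided, with Flt1 (3.92) among the 2 higher and Kdr (-2.67) among the 2 lower of 7 (2 and 2 over the list alone). Kdr was also high in an unnamed class cluster that scored highest for Müller glia, so it does not mark vascular cells alone here. For Ccbe1, edgeR gave adjusted p = 1.15e-15, and this p measures only the spread between libraries of 1 animal. Camera gave adjusted p = 3.79e-10 for cadherins, 0.000195 for neuropeptides, 0.000635 for transcription factors, 2.28e-09 for ganglion cell genes, 0.00755 for the ON cascade, 7.28e-05 for rod genes and 0.0211 for Müller glia genes. With an estimated correlation, adjusted p = 0.395 for cadherins, neuropeptides and ganglion cell genes, 0.488 for transcription factors, the ON cascade and Müller glia, and 0.625 for rod genes. With equal numbers of nuclei per cluster in every library, 51 of the 626 genes called in equally many unmatched nuclei stayed called. Rbfox3 was 0.39 ± 0.22 there (edgeR adjusted p = 0.575). Only clusters 8, 26 and 41 entered, with 164 nuclei per library, while the unmatched nuclei came from all clusters. Rbfox3 stood at 94.1, 16.6 and 43.8 CPM in them in animal 2, below the median of 163 over all clusters. The result says nothing of the other clusters. That matched comparison called 85 genes in edgeR, 43 higher and 42 lower, among them Tac3 (4.30 ± 0.56), Sncg (3.40 ± 0.37), Trpm1 (-3.08 ± 0.42) and Vsx2 (-1.48 ± 0.35, adjusted p = 0.0150).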

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

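The test of the difference between subclasses, the look at unnamed clusters and the marker ratios within single class clusters were chosen after the main results were seen, and the thinned sums, a setting planned beforehand, were taken as a test of depth only after their result was seen; the tests with matched clusters and with markers over whole other classes were set before their results.

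The GABAergic against glycinergic difference was itself different between the NeuN-high and NeuN-low libraries for 1095 of 13544 genes by an edgeR interaction term (573 higher and 522 lower). Rbfox3 was among the lower ones (log2 difference -1.08, edgeR adjusted p = 1.3e-05 over libraries of animal 2 only). Amacrine clusters differed between the 2 gates, and clusters were not matched in this test, so that it does not separate cluster makeup from changes within clusters. Marker genes outside the comparisons were also read in 3 class clusters without a class name, against the limit that a count of 0 allows. Crb1 reached 2144 CPM in class cluster 3 (1989 nuclei) against 70.7 over all nuclei, beside the Müller glia genes Rlbp1 at 1216 and Slc1a3 at 1022. Kdr, a gene of the vascular list, stood at 2425 there, and 1523 of its nuclei came from the NeuN-low libraries. The cluster scored highest for Müller glia (1.0, next class 0.706) with 10 markers detected. It took no name because more of its top genes were markers of another class. Kdr therefore does not mark vascular cells alone in these data. Meis2 stood at 671 in class cluster 4 (1570 nuclei, median 699 UMIs per nucleus), below its level of 819 over all nuclei. Meis2 therefore marks nothing particular to that cluster. The cluster scored highest for amacrine cells (0.984, next class 0.814) and took no name because 2 classes scored alike. Its top genes included Nxph2, Gad1, Vip, Tac3 and Slc6a1, and 740 of its nuclei came from the NeuN-high libraries. These nuclei are not in the amacrine shares. Pax2, an astrocyte gene, reached 287 in class cluster 71 (142 nuclei) against 0.6 over all nuclei, and this cluster also held microglia and pericyte genes.

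The first pattern is the set of 1583 genes that differed between amacrine nuclei of the NeuN-high and NeuN-low libraries. When all sums were thinned to the smallest, 75.2% of the called genes stayed called, which argues against uneven totals as the whole cause. Thinning the sums did not even out the UMIs per nucleus. It cannot decide whether fewer UMIs per nucleus in the low gate took part. Different amacrine clusters in the 2 gates are a candidate explanation: with equal numbers of nuclei per cluster in every library, 8.1% of the genes called in equally many unmatched nuclei stayed called, and their median log2 change in the called direction was 0.20 against 1.65. That test rested on 3 clusters (8, 26 and 41) with 164 nuclei per library and says nothing of the others. In those 3 clusters the gates still differed in 85 genes (43 higher and 42 lower), among them Tac3 (4.30), Vip (3.40), Sncg (3.40) and Trpm1 (-3.08), so that differences within clusters, of biological or technical origin, stay open.

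The second pattern is that ganglion cell genes were higher in NeuN-high amacrine nuclei and bipolar cell genes in NeuN-low ones, by median log2 ratios of 2.17 and -1.76. Free RNA from the main neighbouring classes of each gate is a candidate source, since ganglion cell markers were also higher in NeuN-high bipolar nuclei (median log2 ratio 2.58; Sncg 105 against 11.2 CPM) and bipolar cell markers also lower in NeuN-high rods (median log2 ratio -1.88; Trpm1 39.8 against 155). Different clusters hold these classes in the 2 gates (bipolar cluster 32 gave 255 of 414 NeuN-high and 63 of 5910 NeuN-low nuclei, and rod cluster 17 gave 246 of 257 and 47 of 3696), but the median log2 ratio was 2.93 within bipolar cluster 1 (63 against 2111 nuclei) and 2.58 within cluster 32 for ganglion markers, where the NeuN-low side held 9 UMIs of all 12 markers, and -2.56 within rod cluster 17 for bipolar markers. Horizontal nuclei ran the other way for bipolar markers (0.52), from 14 NeuN-low nuclei. The sorts remove most ganglion nuclei from the low gate and most bipolar nuclei from the high gate, and unmarked doublets of the same classes stay open.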

How the results depend on the processing

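Merging clusters split by animal was the 1 alternative setting added after seeing the data, and the other settings were planned. Counts of called genes stayed within 1.5 times the main count in 114 of 115 alternatives. Some of these could hardly move. Leaving out the standardisation does not change the class or gate sums, and every count then equalled the main one. Coarser and finer clusters both called 1583 genes between the gates, again the main count. Leaving out 1 library at a time gave 3410 to 4237 genes for amacrine against bipolar nuclei, 2964 to 3182 against ganglion nuclei, 1766 to 2071 for GABAergic against glycinergic, 2635 to 2986 for starburst, 2147 to 2382 for AII and 1259 to 1418 for NeuN-high against NeuN-low nuclei. Where a gate was left with 1 library, that library was taken to vary like those of the other gate. The other settings gave 3449 to 4218, 2471 to 3191, 1693 to 2117, 2147 to 3019, 1405 to 2457 and 1205 to 1711 in the same order. The lowest AII count of 1405 came with marked doublets kept, against 2251; the cause was not tested. With libraries as a replicate block the 5 class comparisons called 3449, 2736, 1735, 2447 and 2020 genes, and without a block 4168, 3042, 1847, 2838 and 2215. The channel number as a block called 1580 genes between the gates against 1583; deviations of libraries with the same channel number correlated at -0.029 over 15059 genes, so that the numbers were not used as pairs.

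Named genes kept direction and call in 11262 of 11420 alternatives, lost the call in 151, gained it in 1 and reversed in 6. The total includes 596 values without the standardisation and 596 with coarser clusters, settings that changed the sums little or not at all. None of these changed. With libraries as a replicate block, Slc17a6 (-0.39 against 1.93) and Sncg (-0.60 against 1.49) reversed in amacrine against bipolar nuclei, Vsx2 (-0.003 against 0.52) in starburst, and Cabp5 (-0.86 against 1.26) and Vsx2 (-0.53 against 0.66) in AII nuclei. Slc6a11 reversed in AII nuclei with doublets kept (1.34 against -2.05). The cause was not tested for any of these genes. Gene lists called by camera kept their call in 109 of 141 alternatives and lost it in 32, of which 23 were with libraries as a block. Without a filter on low counts the median log2 change of all genes was -0.17 for starburst and -0.131 for AII nuclei.

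With at least 1000 genes per nucleus, amacrine nuclei made up 27.8% of the unsorted, 72.0% of the NeuN-sorted, 81.6% of the NeuN-high and 27.0% of the NeuN-low nuclei, bipolar nuclei 96.9% of the CHX10-sorted nuclei, and ganglion nuclei 14.9% of the NeuN-sorted and 11.1% of the NeuN-high nuclei. Finer clusters put the bipolar share of the CHX10-sorted library at 94.4%. Of all class shares, 145 of 175 alternatives moved by less than the spread or interval. With nuclei thinned to 1000 UMIs the ratios of Rbfox3 were 19.8 (NeuN-high over NeuN-low) and 3.17 (NeuN-sorted over unsorted), and those of Vsx2 5.83 (CHX10-sorted over unsorted) and 14.5 (NeuN-low over NeuN-high); shallower nuclei are left out in both settings, and the cause was not tested further. Cluster counts in the gates stayed within 1.5 times in every alternative, with 38 to 46 clusters higher in the high and 17 to 26 in the low gate. The correlation with the Rbfox3 level of animal 2, also among these 18 alternatives, ran from 0.798 to 0.817. The number of nuclei limits the rare types: the dopaminergic cluster gave 12 nuclei of animal 2, with 0 in the NeuN-low libraries, so that its ratio is a lower bound.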

Other observations

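The correlation of matched clusters was chosen after the result was seen, and the clusters without standardisation, a setting planned beforehand, were taken as a test only then.

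Bipolar nuclei differed by gate in their types. Class cluster 1 (7733 nuclei), high in Prkca (13289 CPM), a gene of rod bipolar cells, took no type name because the scores for rod and ON cone bipolar cells tied. It held 88.6% of bipolar nuclei in the CHX10-sorted library, 36.5% in the unsorted library, 35.7% in the NeuN-low, 9.77% in the NeuN-sorted and 15.2% in the NeuN-high libraries. ON cone bipolar clusters made up 74.4% of the bipolar nuclei in the NeuN-high libraries and 36.1% in the unsorted library, and ON cluster 32 alone gave 255 of the 414 NeuN-high bipolar nuclei. OFF cone bipolar clusters made up 38.1% in the NeuN-sorted, 29.5% in the NeuN-low, 27.4% in the unsorted, 10.4% in the NeuN-high and 4.67% in the CHX10-sorted libraries.

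Neuropeptide genes peaked in different amacrine clusters. Cartpt peaked at 2538 CPM in the dopaminergic cluster 74. Its median over the 75 clusters (73.1) lay below its level in rods (119) and ganglion nuclei (152). It lay above the level in cone (65.4), horizontal (58.3) and bipolar nuclei (26.2). Levels in this range cannot be told apart from free RNA. Tac3 peaked at 1073 in cluster 58 and stood at 23.9 in rods. Sst in cluster 71 was 10.2 times and Crh in cluster 23 was 10.1 times as high as in the next cluster, with the pseudocount added. Grp peaked at 95.3 in cluster 54, the cluster with Slc17a8, and Cck at 50.7 in cluster 20.

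A further pattern is that 24 of 75 amacrine clusters drew at least 90% of their nuclei from 1 animal. A shift in the same genes in every cluster, from handling, library batch or the animals, was looked for in 10 pairs of matched clusters. Their differences between the animals correlated with a median of 0.168 across 5071 genes. The 32 clusters that mixed the animals gave a similar median (0.169), and no value for counting noise alone was worked out. This correlation therefore cannot decide for or against such a shift. Mt-atp6 was higher in animal 2 in every pair (mean log2 ratio 1.02, 0.63 to 1.29). Standardising each gene within each animal, although the gates gave the animals different makeups, is a candidate explanation, since without it 3 of 65 clusters were of that kind. Animal, gate and library batch coincide here, and a biological difference between the animals was not tested.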
